A study of Homo sapiens with 7 samples.

How the data were processed

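RNA bound by HNRNPH in MCF7 cells was measured by iCLIP2 in 7 samples of 1 group. Per the labels' protocols, cells were irradiated with ultraviolet light, lysates were treated with RNase I, and HNRNPH was immunoprecipitated with an antibody before library preparation and sequencing on a NextSeq 500. Per the submitters' processing notes, FastQC 0.11.5, STAR 2.5.4b and bedtools 2.25.0 were used with genome build GRCh38.p7. The deposited data used here were 1 list of binding sites of 5 nt made from all 7 samples, with chromosome, start, end, strand and a score. The score of the authors is a positive number per site, with 611 sites at a shared ceiling of 708.396. How sites were called, how the score was computed, and whether sites were filtered were not given in the sources used here, and it is not known whether the list used here is complete. Read counts, crosslink counts and values per sample were not analysed here, so the depth per sample is unknown and no count-based normalization or comparison between replicates was made.

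Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used with the hg38 sequence and GENCODE release 44. Sites on chromosomes 1 to 22 and X were kept, 468451 of 468452, and none lay beyond a chromosome end. Each site was represented by its centre, and coordinates are given counting from 1 in GRCh38. Positions on each strand were assigned in the order coding sequence, 3′ UTR, 5′ UTR, non-coding exon, intron of a protein-coding gene and intron of a non-coding gene. Protein-coding genes were read from their protein-coding transcripts, readthrough genes were left out, and where genes overlapped in the same class the shorter gene took the position. Remaining sites were antisense to a gene or outside annotated genes. TUG1, placed in the non-coding list beforehand, is annotated as protein-coding in this release.

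Region shares were compared with 100 random placements that kept the number of sites per gene. Sequence was compared with 20 draws of 1 control position per site in the same gene and region class, at least 100 nt from any site, for the 425160 sites with a control in every draw, and with positions 200 to 500 nt away as an alternative. G-runs (GGG) were sought within 25 nt and G-quadruplex patterns within 50 nt, as 4 runs of at least 2 or 3 G with loops of 1 to 7 nt. Neighbour distances were compared with 100 placements in the same gene and region class, at any position or onto GGG. Splice-site density was taken in 20-nt bins up to 500 nt from internal splice sites, relative to intron more than 500 nt from any exon of the same genes. Internal exons that at least 1 spanning transcript skips were called cassette and those in every spanning transcript constitutive, with a Mantel-Haenszel difference within genes, 1000 label permutations within genes and 1000 bootstrap resamplings of genes. Transcript ends were those of the longest coding transcript per gene.

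Each gene list was compared by its median number of sites per kb with 10000 random lists of genes of like length, drawn from the 100 next shorter and 100 next longer genes of each member. The lists were the HNRNPF/H family, other hnRNP proteins, SR and SR-like proteins, the core spliceosome, other splicing regulators, targets of HNRNPH or HNRNPF from the literature, luminal breast and oestrogen response, epithelial-mesenchymal transition, apoptosis, cell cycle, cytosolic ribosomal proteins, nuclear long non-coding RNAs, and markers of immune cells, fibroblasts and endothelium, neurons and hepatocytes. BCL2L1, CCND1 and CDH1 are each in more than 1 list. Which marker genes MCF7 cells express was not measured.

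The comparisons, lists, controls and placements, the rule for named genes and most alternatives were fixed before the data were examined. That rule named the 10 genes with the most sites, the 10 protein-coding genes with the most sites per kb among those with at least 20, every member of the HNRNPF/H family and of the literature targets, and the 3 members with the most sites of each other list. It also named up to 5 members with a site in each list of another cell type, the MST1R region from exon 10 to exon 12, and the 5 sites with the highest score in separate genes. Because 611 sites tie at the ceiling, the 5 genes with the most ceiling sites were named in place of the last.

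Several choices were made only after the data were seen. These were the 100-nt windows that summarise splice-site density and their gene-matched expectation, the ratio of the first 100 nt to 400 to 500 nt downstream of transcript ends, and the use of sites assigned to genes as the base of the intron share. The tables of introns by position and length, the linking of sites within 100 nt into clusters, and the rule for ties were also chosen then. So was the measure of repeated sequence, a 13-nt sequence with at least 10000 copies on both strands of the chromosomes analysed, for which no other length or number of copies was tried. A value was called different when it lay outside the range of placements or permutations, or when its difference from the reference exceeded the 95% normal interval from the delete-one-chromosome jackknife, a rule also set after the data were seen. A gene list was called above random lists beyond their central 95%.

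The alternatives covered the score (above the median, 234225 sites, and above the 90th percentile, 46845 sites), window sizes, transcript choice, the order of region classes, other controls, exon flanks and restriction to genes with a site. Share of sites in repeats marked in the reference was planned but not run, since the sequence used here carries no such marks. The procedures were tested on simulated data, where 18 of 18 checks lay within preset tolerances. Most of these checks used 437279 simulated sites, 1 read 2 known windows and 1 used 50000 simulated pairs of normal values. With no planted effect, the GGG difference was -0.0887 percentage points and the ratio after 5′ splice sites 1.00. Planted values of 69.8% for GGG, 59.3% for neighbours and 2.00 for density after 5′ splice sites were recovered as 69.6%, 60.0% and 2.04. A planted cassette difference of 6.50 points was recovered as 7.51, above the planted value because windows of neighbouring exons overlap. All 20 lists with raised site numbers were recovered, and 1 of 20 random lists lay above the central range. These lists were drawn from genes with a site and compared only with such genes. The comparison of gene lists with all genes was therefore not checked in this way.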

Results

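The RNA contacts of the heterogeneous nuclear ribonucleoprotein HNRNPH, a nuclear protein that regulates splicing, were mapped in MCF7 cells, an established epithelial line of luminal, oestrogen receptor-positive breast cancer. The assay was iCLIP2, in which ultraviolet light ties the protein to RNA, the protein is immunoprecipitated, and sequencing of the trimmed RNA places the contact at single-nucleotide resolution. All 7 samples were replicates of 1 group, with no control group, and their data came as 1 pooled list of binding sites. No value per sample was in the list, so the depth of each sample was unknown, no spread between replicates could be given, and no p-value was computed. Sites and genes are not replicates. Standard errors (SE) come from leaving out each chromosome in turn, and binomial intervals cover counting error only.

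The list held 468452 binding sites, each 5 nt wide, of which 468451 lay on chromosomes 1 to 22 and X and were used. The plus strand held 248131 sites (53%) and the minus strand 220320 (47.0%). Chromosome 17 held the most sites, 40647, ahead of chromosome 1 with 39725, and chromosome 18 the fewest, 3638. On their own strand, 437279 sites (93.3%) fell in 12547 annotated genes, and 10100 of 19320 protein-coding genes held at least 1. The median gene with a site held 13, 955 genes held at least 100, and the 100 genes with the most sites held 15.8% of the sites in genes. The score that the authors gave each site had a median of 12.4 (quartiles 5.96 and 26.1), and 611 sites shared its highest value, 708.396.

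IGF1R, which encodes the receptor of insulin-like growth factor 1, held the most listed sites. The next 9 genes included RXRA, a nuclear receptor gene, GREB1, a classical oestrogen-induced gene, and NCOA3, which encodes a nuclear receptor coactivator. SULF2, an extracellular sulfatase, the receptor gene GFRA1, the RNA-binding protein gene MSI2, the adenylyl cyclase gene ADCY1, BCAS3 and GSE1 made up the rest. Nearly all of the sites in these genes were intronic. IGF1R (GRCh38, chromosome 15, 98648539 to 98964530, plus strand) held 3082 sites, 2964 of them in introns, or 9.77 per kb of gene. GREB1 (chromosome 2, 11482341 to 11642788, plus strand) held 1707 sites, 10.7 per kb, of which 68 were in coding sequence. RXRA (chromosome 9, 134317098 to 134440585, plus strand) held 1716 sites at 13.9 per kb. The others ranged from 1276 sites in ADCY1 to 2079 in GSE1, with 1973 in BCAS3, 1657 in MSI2, 1436 in SULF2, 1400 in GFRA1 and 1287 in NCOA3. RNA level and gene copy number were not measured, and a site count mixes both with binding.

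Mostly short genes had the densest sites. KRT19, a keratin of epithelial cells, led the protein-coding genes with at least 20 sites, followed by the thymosin gene TMSB4X. The autophagy kinase gene ULK1 and the cyclin gene CCND1, which drives entry into the cell cycle, stood out by holding many sites as well as dense ones. KRT19 (chromosome 17, 41523617 to 41528308, minus strand) held 98 sites, or 20.9 per kb, 27 of them in coding sequence. TMSB4X (chromosome X, 12975110 to 12977227, plus strand) held 42 sites, 19.8 per kb, and 24 of these lay in its 5′ UTR. ULK1 (chromosome 12, 131894622 to 131923150, plus strand) held 479 sites at 17.9 per kb, and CCND1 (chromosome 11, 69641156 to 69654474, plus strand) held 237 at 17.8 per kb, with 49 in its 3′ UTR. ZNF768, PHPT1, OAZ1, ERF, PPDPF and ARRDC1 completed the 10 densest genes at 17.2 to 18.1 sites per kb.

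The gene of HNRNPH itself was among those with listed sites. HNRNPH1 carried sites in its introns, its coding sequence and its 5′ UTR, and its paralogues HNRNPH3 and HNRNPF also carried many, whereas GRSF1, the mitochondrial member of the family, carried few. HNRNPA2B1, which encodes another abundant hnRNP protein, had 43 sites in its 3′ UTR, and CELF1, which encodes a splicing and decay factor, had most of its exonic sites there. HNRNPH1 (chromosome 5, 179614178 to 179634784, minus strand) held 174 sites, 8.44 per kb: 106 in introns, 33 in coding sequence, 26 in the 5′ UTR and 9 in the 3′ UTR. HNRNPH3 (chromosome 10, 68331174 to 68343193, plus strand) held 142 sites at 11.8 per kb, HNRNPF 85, HNRNPH2 18 and GRSF1 13. The 3 members with the most sites in each of the other lists of splicing genes were named by rule, and not all members held a site. Their counts were 215 for HNRNPA2B1, 183 for HNRNPC, 174 for PCBP2, 242 for SRPK2, 193 for SRRM2, 109 for TRA2A, 192 for U2AF2, 137 for SNRNP70, 124 for SF1, 184 for CELF1 (91 in its 3′ UTR), 158 for SFPQ and 135 for RBM4.

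Lists of genes asked which functional groups carry more sites than genes of like length. Luminal breast and oestrogen response genes, cytosolic ribosomal protein genes, hnRNP genes outside the HNRNPF/H family, genes of SR and SR-like proteins (serine- and arginine-rich splicing factors) and other splicing regulator genes all carried dense sites. Genes of epithelial-mesenchymal transition did not differ from random lists as a group, although the epithelial cadherin gene CDH1, the signal transducer gene SMAD3 and the integrin gene ITGB4 each held over 200 sites. Most markers of immune cells, of fibroblasts and endothelium, of neurons and of hepatocytes had no listed site. The median density of the 24 luminal genes was 5.20 sites per kb, and all 24 held a site. It was 5.09 per kb for ribosomal protein genes (26 of 27 with a site), 3.73 for the other hnRNP genes (22 of 24), 2.18 for SR genes (21 of 22), 1.39 for other splicing regulators (28 of 30) and 2.13 for nuclear long non-coding RNAs (5 of 8). Each of these 6 medians lay above all 10000 length-matched random lists. The random lists were not matched on RNA level, so a high rank does not separate RNA level from binding.

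The HNRNPF/H family (3.61 per kb, 99.2nd percentile of the random lists) and the core spliceosome (0.734 per kb, 30 of 32 genes with a site, 99.9th percentile) also lay above the central 95% of random lists. The same held for apoptosis genes (0.654 per kb, 18 of 20, 99.5th percentile) and cell cycle genes (0.738 per kb, 23 of 24, 99.6th percentile). When only genes with at least 1 site were compared, these 4 lists lay inside that central range, at percentiles of 95.1, 78.9, 71.8 and 50.8 in the same order, and 7 of the 11 lists stayed above it. The epithelial-mesenchymal transition list (13 of 18 genes with a site) lay at the 65.7th percentile of all genes and at the 40.4th among genes with a site. A site was listed for 1 of 14 immune, 2 of 14 fibroblast and endothelial, 4 of 16 neuronal and 0 of 12 hepatocyte markers. These were CD68 with 2 sites, ACTA2 and COL1A1 with 1 each, SYT1 with 46, MBP with 7, and GAD1 and SLC17A7 with 1 each. MBP and PLP1 in the neuronal list are myelin genes and not markers of neurons themselves. Each of these 4 lists had a median of 0, the lowest value possible, at percentiles of 26.8, 7.45, 16.0 and 15.2, so the comparison could not have placed them below random lists. Among genes with a site the percentiles were 13.2 for the 1 immune marker, 0.13 for the 2 fibroblast and endothelial markers and 2.81 for the 4 members of the neuronal list. Of these, only that of the fibroblast and endothelial list lay below the central 95%. Among the best-covered members of the remaining lists, ESR1, the oestrogen receptor gene, held 960 sites, SMAD3 792, CDH1 558 and ITGB4 227. MCL1 held 86, CFLAR 64, E2F1 80, CDC25B 69, RPS19 66, RPS24 62 and RACK1 61, and the nuclear RNAs KCNQ1OT1, TUG1 and GAS5 held 292, 49 and 33.

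Genes whose splicing or processing is linked to HNRNPH or HNRNPF in the literature were examined as a further list. MADD, which encodes a death-domain adaptor, and BCL2L1, the apoptosis regulator with a long and a short isoform, held mostly intronic sites. The tumour suppressor gene TP53 had sites in its 3′ UTR, and the telomere-binding protein gene TERF2 had sites in coding sequence. MST1R, the receptor gene in which skipping of exon 11 is the known splicing event, had no listed site. MADD held 129 sites, BCL2L1 79 (69 in introns), TP53 60 (17 in the 3′ UTR), NF1 58, TERF2 25 (11 in coding sequence), ARAF 21 and FGFR2 5. The list's median was 0.899 per kb, the 99.2nd percentile of random lists of all genes and the 97.6th of genes with a site. In MST1R (chromosome 3, minus strand) the region from exon 10 to exon 12 (49895715 to 49896404, 690 nt) and exon 11 itself (49895961 to 49896107, 147 nt) held 0 sites, as did the whole gene. No site in the list does not show that a gene was not bound, since the detection limit per gene is unknown, and so is whether the list used here is filtered or complete.

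The distribution over transcript regions asked where on the RNA the protein was found. Introns of protein-coding genes held most sites. Against random positions in the same genes, untranslated regions were over-represented, the 5′ UTR most, and coding sequence was under-represented. Introns held slightly fewer sites than their length alone would give. Coding-gene introns held 341557 sites, 72.9% of all (95% exact Clopper-Pearson interval 72.8 to 73.0%). The 3′ UTR held 36167 (7.72%, 7.64 to 7.80%), the 5′ UTR 15830 (3.38%, 3.33 to 3.43%) and coding sequence 11997 (2.56%, 2.52 to 2.61%). Non-coding exons held 10165 sites (2.17%) and introns of non-coding genes 21563 (4.60%). Relative to 100 random placements that kept the number of sites per gene, the ratio was 2.08 ± 0.122 (SE) in the 5′ UTR, 1.54 ± 0.0356 in the 3′ UTR, 0.499 ± 0.0190 in coding sequence, 1.08 ± 0.0204 in non-coding exons and 0.975 ± 0.00571 in coding-gene introns. Introns of either kind held 83.0 ± 0.679% of sites in genes, against 85.2% on average in the placements. This deficit ended when overlapping positions were counted as intron before exon, where sites and placements both gave 88.8%.

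Exons and introns were also compared by density within coding genes. Exons held more sites per kb than introns, but most of that excess came from differences between genes. Exons here pooled coding sequence with untranslated regions. Relative to placements, coding sequence stood at 0.499, the 3′ UTR at 1.54 and the 5′ UTR at 2.08, so the excess does not describe coding sequence. RNA levels of exons and introns were not measured, so the density does not separate RNA level from binding. Pooled over 9976 genes, exons held 1.27 and introns 0.503 sites per kb, a ratio of 2.52 ± 0.139. Matched within genes, the ratio was 1.22 ± 0.0559, and above the 90th percentile of the score the pooled ratio was 4.24.

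The sequence around sites was compared with positions in the same gene and region at least 100 nt from any site, because HNRNPH is known to bind runs of guanine. G-runs surrounded most sites in every region of the transcript, and patterns of 4 close G-runs that can fold into a G-quadruplex were more frequent than at control positions. Uracil joined guanine at the site itself, which is a base that crosslinks readily under ultraviolet light, and cytosine was depleted. GGG lay within 25 nt of 87.6% of sites and 45.4% of controls (20 draws, 45.2 to 45.5%), a difference of 42.2 ± 1.20 percentage points over 425160 sites that was positive on 23 of 23 chromosomes. Against positions 200 to 500 nt away, the shares were 87.6% and 57.2%. Patterns of 4 runs of at least 2 G within 50 nt marked 64.3% of sites and 18.4% of controls (46.0 ± 0.959 points). The strict form, with at least 3 G per run, marked 12.3% and 0.887%, or 11.4 ± 0.377 points. Against positions 200 to 500 nt away, the looser pattern marked 64.7% and 31.9%, and the strict form 12.9% and 3.27%. Controls were not matched on G content, which was 36.4% within 25 nt of sites and 23.3% in controls. The excess of G-quadruplex patterns was therefore not separated from the excess of guanine and of G-runs. In the central 5 nt, G made up 44.7% of bases against 23.3% in controls, U 34.7% against 28.1%, A 12.5% against 24.8% and C 8.13% against 23.7%.

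**Figure D1:**
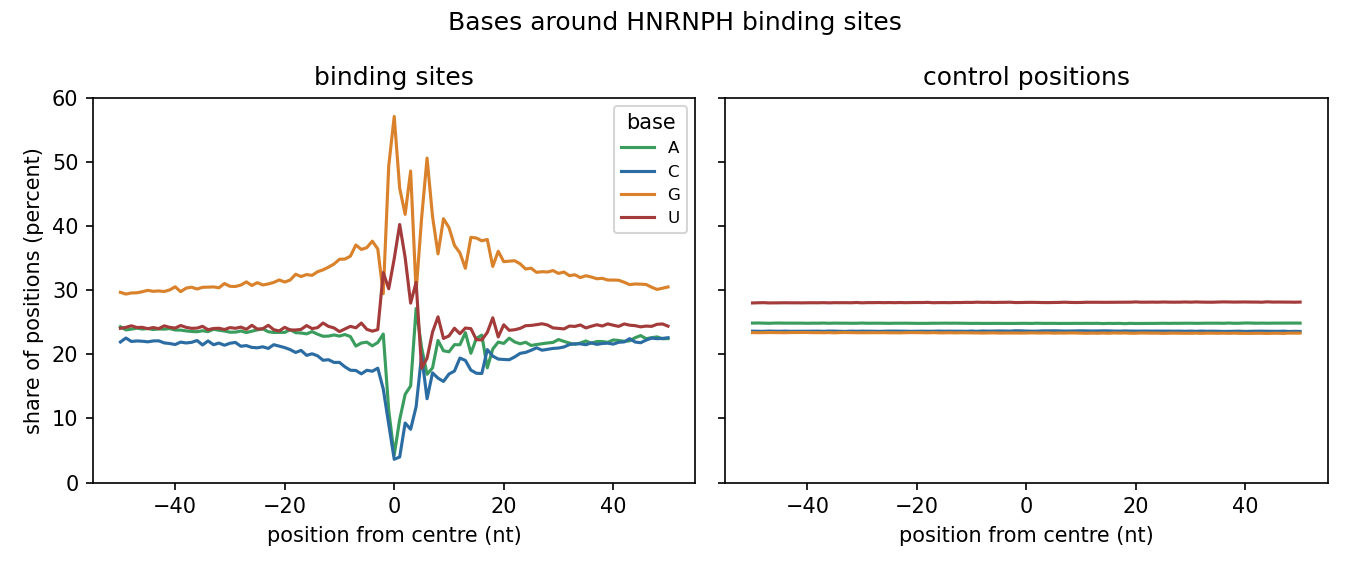
Percentage of each base by position from 50 nt before to 50 nt after the site centre, for sites and control positions. Guanine is raised over the whole window and highest near the centre, while the controls average 23.3%.

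Among sense regions of genes, the 5′ UTR had the highest share of strict G-quadruplex patterns, 18.0% of sites against 2.45% of controls, compared with 12.2% against 0.876% in coding-gene introns. The GGG shares of sites and controls were 89.0% and 56.1% in the 5′ UTR, 82.7% and 41% in the 3′ UTR, 81.4% and 49.0% in coding sequence, and 88.3% and 45.4% in coding-gene introns. Among all pentamers, GGGGG was the most enriched, at 9.07 times its frequency in controls, followed by GUGGG (6.68), GGGGU (6.59), GGGGA (6.41) and GGGUG (6.40). GGG was part of 21 of the 25 most enriched pentamers, and the others were GGUGG (5.52), GGAGG (4.5), GGUUG (3.62) and GGCGG (3.60). The most depleted were AUUAC (0.316), CUCAA (0.336) and ACCUC (0.345). Odd and even chromosomes gave the same 10 most enriched pentamers, with a correlation of 0.996 across pentamers, which are not independent replicates.

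Distances between sites asked whether the protein sat on RNA in clusters. Sites lay close together more often than random positions, or random G-runs, of the same gene and region would. The largest cluster lay in an intron of PNPLA7, a lysophospholipase gene, followed by clusters in introns of the phosphatase subunit gene PPP2R2D and of EIPR1. Intronic clusters in ULK1 and in BMP7, a gene of the bone morphogenetic protein family, came next. Another site lay within 100 nt of 83.4 ± 0.324% of the 437279 sites in genes, against 40.1% in random placements (highest of 100, 40.2%) and 44.3% in placements onto GGG (highest 44.5%). Placements onto GGG within 1 kb of each site gave 62.7% (highest 62.8%). Within 30 nt the shares were 63.9 ± 0.140%, 16.8% and 21.9%, and within 300 nt 92.0 ± 0.406%, 63.6% and 65.6%. Another site 31 to 100 nt away was found for 54.4 ± 0.725% of sites, against 36.2% on GGG. Above the 90th percentile of the score, the share within 100 nt was 55.2%, against 22.9% in placements. Linking sites within 100 nt gave 194941 clusters, of which 78275 (40.2%) were single sites and 20130 had at least 5 sites. The PNPLA7 cluster (chromosome 9, 137517548 to 137519211, minus strand, 1664 nt) held 61 sites. The next held 41 in PPP2R2D (chromosome 10, 131918227 to 131919865, plus strand), 36 in EIPR1 (chromosome 2, 3328415 to 3329518, minus strand), 35 in ULK1 (chromosome 12, 131902096 to 131903336, plus strand) and 35 in BMP7 (chromosome 20, 57198417 to 57199895, minus strand).

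**Figure D2:**
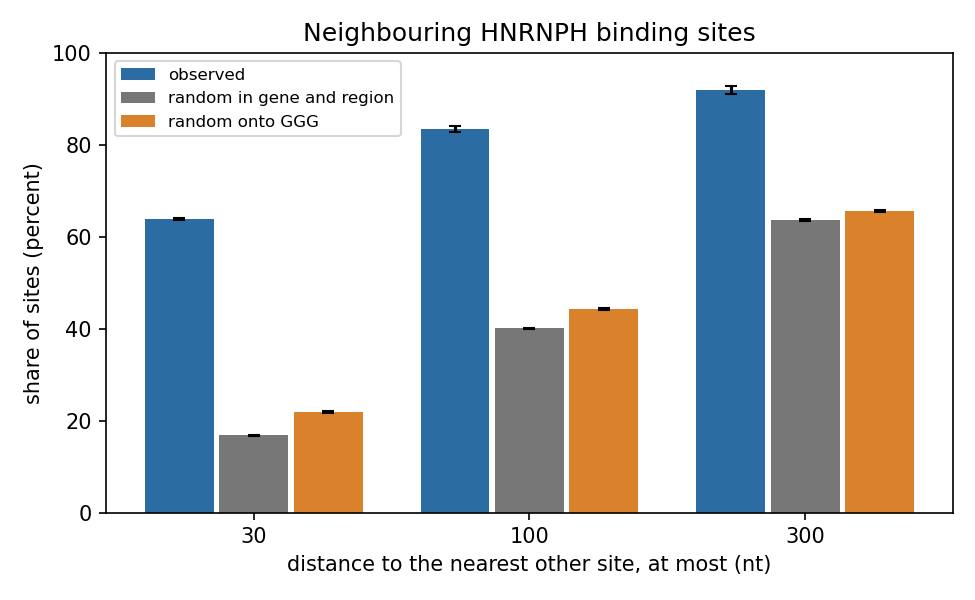
Percentage of sites with another site within 30, 100 and 300 nt, for observed sites, random placements and placements onto GGG in the same gene and region. The observed share lies above both kinds of placement at each distance, with 83.4% against 40.1% and 44.3% at 100 nt.

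Splice sites were examined because HNRNPH acts on splicing from positions near exons. Of the stretches on either side of splice sites, the start of introns, downstream of 5′ splice sites, had the highest density, and the excess extended far into the intron. The last stretch of the intron, where the polypyrimidine tract and the branch point lie, was depleted. So were the 100 nt of exon next to either splice site, taken as a whole. Upstream of that depleted stretch, introns lay above their interior on this side as well. In the first 100 nt of introns the density was 1.82 sites per kb against 1.04 from intron interiors of the same genes, a ratio of 1.75 ± 0.0561 (18777 sites, 7485 genes). The peak lay 20 to 39 nt into the intron, with a ratio of 2.20 ± 0.0640, and from 60 to 499 nt the bins stayed between 1.53 and 1.76. In the last 100 nt of introns the ratio was 0.848 ± 0.0342, falling to 0.207 ± 0.0125 in the last 20 nt, after 1.41 ± 0.0677 from 80 to 61 nt before the exon, and farther upstream, out to 500 nt, the bins lay between 1.11 and 1.27. In exons it was 0.445 ± 0.0284 in the first 100 nt and 0.768 ± 0.0525 in the last 100 nt. Without first introns the ratio was 1.22 ± 0.0325 in the first 100 nt of introns and 0.433 ± 0.0239 in exon ends before 5′ splice sites. The reference for these 2 ratios still included the interiors of first introns.

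**Figure D3:**
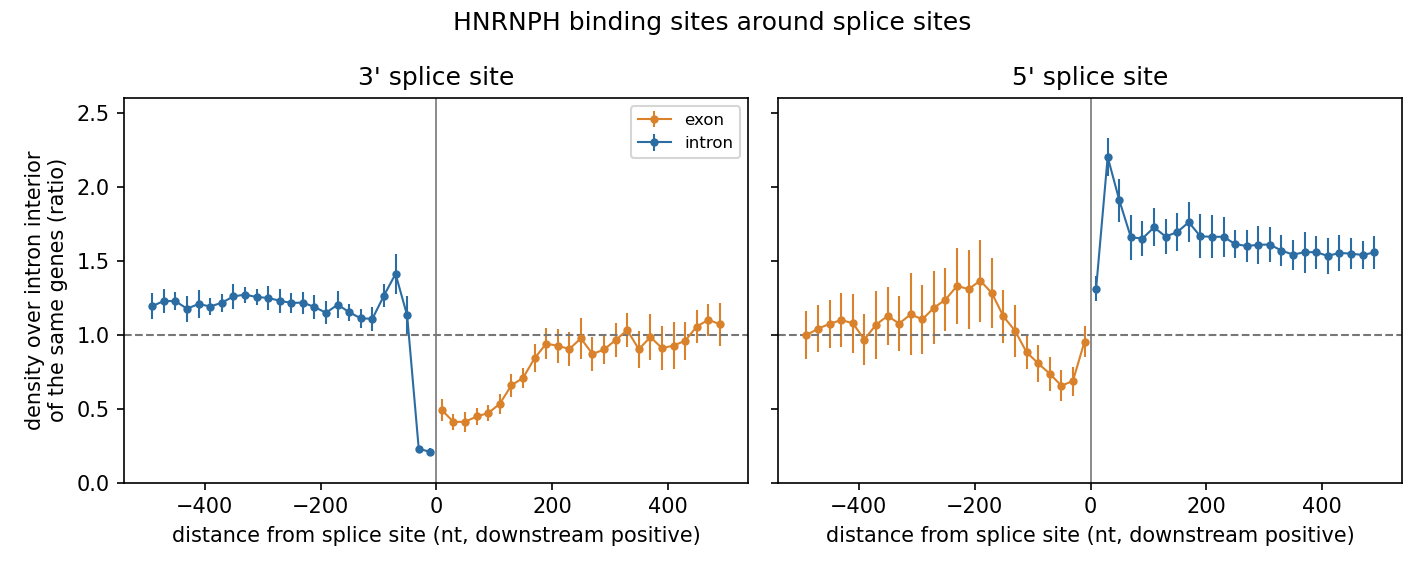
Site density in 20-nt bins up to 500 nt from 3′ and 5′ splice sites of protein-coding genes, relative to intron interiors of the same genes, with jackknife SE. The density peaks at 2.20 shortly after the 5′ splice site and is lowest, at 0.207, just before the 3′ splice site.

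Annotated cassette exons, which some transcripts of a gene skip, were compared with constitutive exons of the same gene to ask whether alternatively used exons carry more binding. Cassette exons and the introns beside them held sites more often. The excess lay on both sides and in the exon itself, and was larger in the upstream than in the downstream intron by point estimate, a difference that was not tested. The shares given here are averages over genes with the weights of the Mantel-Haenszel difference, and not shares of all exons pooled. With 300 nt of intron on each side, 25.5% of cassette and 19.99% of constitutive exons held a site, a within-gene difference of 5.5 percentage points. Its 95% interval over 1000 resamplings of genes was 4.82 to 6.11, over 6943 genes with 29256 cassette and 63386 constitutive exons. Shuffling the labels within genes 1000 times gave at most 0.727. The upstream intron alone gave 15.6% against 10.7% (4.88 points, 4.34 to 5.44) and the downstream intron 16.0% against 12.3% (3.69 points, 3.11 to 4.25). The exon body alone gave 4.99% against 3.12%, a difference of 1.86 points, and sites above the 90th percentile of the score gave 3.10 points.

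Ends of protein-coding transcripts were examined because HNRNPH and HNRNPF are also linked to polyadenylation. Density was highest in the 3′ UTR about 100 nt before the annotated end, fell to its lowest shortly before that end, and rose again downstream of it. Whether sites can be detected equally well close to the end of an RNA was not tested. The fall therefore does not show less binding there. Positions downstream of the end could still belong to longer transcripts of the same gene. The rise therefore does not show sites past the end of the gene. Over 9442 transcript ends, the density was 2.35 sites per kb in the densest 20-nt bin, which starts 120 nt before the end, and 0.307 from 40 to 21 nt before it. It was 0.769 per kb in the first 100 nt downstream and 0.544 at 400 to 500 nt downstream, a ratio of 1.41 ± 0.130. Above the 90th percentile of the score the ratio was 1.71 ± 0.409, no longer separable from 1. The last 100 nt before the end held 1.04 sites per kb, and downstream over upstream density was 0.736 ± 0.0409.

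The authors' score was compared with sequence and region to ask whether it varies with G-runs. What the score measures is not known here, and it was not separated from RNA level. Sites in untranslated regions had higher scores than intronic sites, and sites with a neighbour had higher scores than isolated ones. Among the genes with the most sites at the highest score, MLPH, a melanophilin gene, led, and DDX6, an RNA helicase gene, the splicing factor gene SRSF6, DYNLL2 and the non-coding RNA DSCAM-AS1 followed. The median score rose from 9.71 for 23490 sites without a G-run within 50 nt to 15.3 for 143735 sites with 5 or more. Spearman's rho was 0.145 ± 0.00379 across all sites and 0.206 ± 0.00267 on average within 5030 genes of at least 20 sites, of which 87.0% had a value above 0. The median score was 16.1 in the 5′ UTR, 15.1 in the 3′ UTR, 12.5 in coding sequence and 12.1 in coding-gene introns. It was 13.5 for sites with a neighbour within 100 nt and 8.77 without. MLPH held 49 sites at the highest score, DYNLL2 11, and DDX6, SRSF6 and DSCAM-AS1 10 each. The first of these in DDX6 (chromosome 11, 118748167 to 118748171, minus strand, 3′ UTR) lies in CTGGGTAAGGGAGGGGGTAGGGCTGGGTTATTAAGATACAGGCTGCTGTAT, written as DNA, with 5 G-runs in 51 nt. The first in DYNLL2 (chromosome 17, 58089504 to 58089508, plus strand, 3′ UTR) had 0 G-runs in its window.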

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

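Both tests in this part were chosen after the numbers of these sites were known, and before the values the tests measure were seen. Sites outside the annotated sense strand of genes enter none of the comparisons by gene, and are described here because they hold signal that those comparisons leave out. Their number alone does not make them unexpected. They comprised 10397 sites antisense to a gene (2.22%) and 20775 sites outside annotated genes (4.43%). Their median scores were 11.3 and 12.2, beside 12.4 for the whole list.

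Assignment of reads to the wrong strand would place the G-runs of antisense sites on the opposite strand. GGG lay within 25 nt on their own strand for 91.7% of them and on the opposite strand for 40.3%, a difference of 51.4 ± 1.34 percentage points, which argues against wrong strands as the main source. Only 7.61% had a site on the sense strand within 50 nt. Sites outside genes may partly lie on RNA that runs past annotated gene ends, since 27.5% lay within 10 kb downstream only and 16.0% within 10 kb upstream only of a gene with a site, a difference of 11.5 ± 2.41 points. Transcripts missing from the annotation stay open for both kinds, and with 1 group of samples no biological explanation was tested.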

How the results depend on the processing

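Of 68 alternative values for the main comparisons, 65 kept their direction and their side of the threshold. The excess of GGG and of G-quadruplex patterns, the excess of close neighbours, the densities after and before splice sites and the cassette exon difference did so under each alternative run, including above the 90th percentile of the score. The intron share became 88.8% in sites and in placements when intron was put before the exonic classes, which by construction hides exonic sites that other transcripts cover with an intron. Above the 90th percentile of the score the ratio downstream of transcript ends was 1.71, larger than the 1.41 of all sites but with an SE of 0.409 from far fewer sites. Among genes with at least 1 site, 7 gene lists lay above the random lists, against 11 among all genes, and the percentile of the epithelial-mesenchymal transition list crossed the middle, from 65.7 to 40.4; comparing bound genes only removes the part of the excess that comes from having any site. Of 72 values for single lists and regions, 66 were the same, 4 were no longer beyond the random lists, 1 (fibroblast and endothelial markers, percentile 0.13 among genes with a site) became so, and 1 turned. Hepatocyte markers gave no value among genes with a site. Alternatives chosen after the data were seen were the gene-matched exon ratio, neighbours at 31 to 100 nt, placements within 1 kb, splice-site density without first introns, longer flanking introns, wholly coding exons and sites without repeated sequence. The share of sites in marked repeats was not run. No paired analysis was possible because the 7 samples form 1 group and their sites were pooled. Depth per sample is unknown, so what it limits could not be measured.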

Other observations

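The test for a split footprint was chosen after its result was seen. The tests of introns by position, of first introns, of repeated sequence, of placements within 1 kb, and of the flanks and coding state of exons were chosen after the patterns were seen, but before their own values.

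First introns, which lie next to promoters and 5′ UTRs, carried denser sites than the average over all introns of their genes. Their density was 1.28 ± 0.0228 times that expected from all introns of the gene (109762 sites), against 0.853 ± 0.0270 in last introns and 0.902 ± 0.00721 in the introns between. By length, introns of up to 200 nt stood at 0.894 ± 0.0262, those of 200 to 500 nt at 1.18 ± 0.0222 and those of 500 to 1000 nt at 1.13 ± 0.0193, and the longer classes ranged from 0.927 to 1.03. Without first introns, the ratio in the first 100 nt after 5′ splice sites was 1.22, beside 1.75 with them, and the ratio in the last 100 nt of introns was 0.791. The intron interiors used as reference were still those of all introns of the gene, first introns included. Since first introns carried denser sites, the ratios without them may be too low. How much of the excess after 5′ splice sites lies in first introns was therefore not settled.

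Sequences that occur in many copies across the genome, such as transposable elements, were less frequent at sites than at control positions of the same gene and region. A repeated 13-nt sequence lay within 25 nt of 13.5% of sites and 23.4% of controls, a difference of -9.91 ± 0.776 percentage points. Against positions 200 to 500 nt away the shares were 13.4% and 15.2%. Whether reads from repeated sequences could be placed as well as others was not tested. The lower share at sites therefore does not show less binding to such sequences. GGG lay within 25 nt of 89.1% of sites without such a sequence and of 44% of their controls, and of 78.5% and 49.9% with one.

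Some genes of the fixed lists had no listed site although most others in their list did, and they were picked out after their values were seen. HNRNPL and HNRNPR held 0 sites beside 215 in HNRNPA2B1, CLK2 held 0 beside 193 in SRRM2, PRPF8 held 0 beside 192 in U2AF2, and RPS18 held 0 beside 66 in RPS19. The abundant nuclear RNAs MALAT1 and NEAT1 also held 0, beside 292 in KCNQ1OT1. Each of these genes held 0 sites on either strand over its whole length. Whether the list used here is complete for these genes is not known, so their values show neither presence nor absence of binding. The percentiles of their lists count them as 0.

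The close spacing of sites was weighed against 3 technical explanations. A footprint narrower than 31 nt, split into adjacent sites, would leave no excess beyond it. Another site lay 31 to 100 nt away for 54.4% of sites, against at most 36.3% in gene-wide placements onto G-runs. Wider footprints were not tested, as the width of a footprint is unknown here. Placements within 1 kb were not made for this distance, so a split footprint stays open. RNA level that changes along a gene over kilobases would be shared by G-runs within 1 kb. Placements onto those gave at most 62.8% with a neighbour within 100 nt, against 83.4% observed. Such changes may account for part of the excess over 44.3% but not for all. RNA level that changes over shorter stretches was not tested. Sequences with at least 10000 copies are argued against as the whole source. Of the sites without one, 82.0% had a neighbour, against at most 42.1% in their placements. Repeats with fewer copies, such as local tandem repeats, escape this measure and were not tested. Several protein contacts along G-rich stretches stay open as a hypothesis, as does the unknown rule by which sites were called, and with 1 group of samples no biological explanation was tested.

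The excess of sites at cassette exons was weighed against 3 explanations from exon architecture. More G-runs around cassette exons are argued against as the whole source, since sites per G-run were 1.27 ± 0.0204 times as frequent there as around constitutive exons, with 14.6 and 14.2 GGG positions per window. Longer flanking introns would end the difference where both introns have at least 300 nt, yet it was 4.08 points there, above the highest permutation at 0.976. A place in untranslated regions is argued against by wholly coding exons, where it was 4.44 points, above 0.939. Exons were not matched on their place in the gene. Those beside first introns, which carried denser sites, were not left out, so a difference in place stays open. Slower removal of the introns beside cassette exons, which would leave more of that RNA to be crosslinked, could not be tested without RNA levels, and no biological explanation was tested.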
